A study of Saccharomyces cerevisiae with 50 samples.

How the data were processed

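The data were 50 two-channel array hybridisations of budding yeast RNA, read from the deposited value table of the series. Each of 25 time points after release from alpha factor was hybridised with the sample in Cy3 (replicate 1) and with the sample in Cy5 (replicate 2), each time against RNA of an asynchronous culture in the other dye, per the labels. The groups are the time points, and time, dye and date batch were taken from the labels. The labels' titles gave 2 date batches for replicate 1 and 6 for replicate 2, and no label names a second culture.

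The deposited values are log ratios, and neither the base nor the direction is given in the sources used here. The values were taken as log10 of Cy5 over Cy3 as made by the authors. For the base, the deposited values end exactly at -2 and 2, a 100-fold limit on a log10 scale. A course over whole cycles set against a pool of the same cells also ties each gene's mean to its variance, with an expected slope of -1.15 for log10, -0.500 for natural logs and -0.347 for log2. The observed slopes lay between -1.12 and -0.970 over all genes in 4 windows and between -2.07 and -1.47 over 103 list genes. The base remains an inference, and all log2 values and folds below rest on it. For the direction, the arrays of a time point correlated with a median r of -0.472 as deposited, so replicate 1 was turned. That the result is sample over reference was read from pheromone genes at 0 min and is likely rather than stated. Turned the other way the slopes above would be positive, while the expected slope is negative for each base, but every direction below rests on this reading. Within 1 orientation the lowest correlation between arrays was 0.0753 (Cy3) and 0.0466 (Cy5). Array medians lay between -0.0046 and 0.0345 log10 units. How the authors normalized or centred the arrays is not given in the sources used here.

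The table held 6217 lines, of which 13 were controls or incomplete names and were left out. Of 6204 open reading frames, 5704 matched a locus tag of the R64 gene table and took its symbol, and 500 kept the deposited name. That table was used only for names and coding lengths, and no coordinates are given. Of the values, 438 were missing, and 709 lay at the limit and were kept. Values were converted to log2, turned to sample over reference and averaged over the dye-swap pair, which left 1 value per time point. A gene needed 20 of 25 time points. No gene was incomplete after averaging, so this filter and its alternatives (all 25, or at least 8) removed nothing and say nothing about stability.

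Statistics were computed in R 4.3.3 with limma 3.58.1, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The period was the value between 40 and 90 min, in steps of 1 min, that gave the highest mean R squared of a cosine with a linear trend over 60 genes of 4 textbook lists (0.685 at 66 min and 0.650 at 60 min), with a bootstrap of 1000 draws over genes. Periodicity was limma's moderated F test on the sine and cosine with a linear time term. Amplitude is the fitted distance from the mean to the peak in log2 units, and peak times carry delta-method standard errors (median 2.35 min over called genes). Lists were tested with two-sided Fisher's exact tests, and the order of mean peak times with 10000 permutations of gene labels. The cycles were compared by the interaction of sine and cosine with cycle, and for the level by the cycle term with common sine and cosine. The release comparison used limma on 8 time points, with camera at a preset correlation of 0.01 and at an estimated correlation, and fry. Dye bias used limma on the differences within pairs.

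The genes named in the text followed a rule fixed, like the designs, the gene lists and the alternatives set beforehand, before the data were examined. The rule took the 12 largest amplitudes among genes periodic also in each dye orientation alone, the 10 largest changes each way for the release, the 5 largest each way for amplitude and for level, the 3 largest each way for dye bias, all with the same sign in both orientations where that applies, and up to 4 passing members of each list. Any list member may be named with its outcome, and every transcription regulator with its peak time. The values of 1 gene are not reported here, although it counts in the totals. The 23 lists held 373 names, and 357 distinct genes of them were measured. They cover G1 regulators, DNA replication, cohesion and repair, histones, spindle and kinetochore, the CLB2, SIC1 and MCM clusters, transcription regulators, pheromone response, MATa-specific, MATalpha-specific, meiosis, ribosomal protein, ribosome biogenesis, stress, glycolysis, methionine, phosphate, cell wall, oxidative phosphorylation, proteasome and reference genes. A further list of 31 amino acid synthesis genes was added after the data were seen.

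The computations were tested on simulated courses of 5832 genes with known changes. Periodic genes were recovered at 61.2%, 89.6% and 95.5% for amplitudes of 0.25, 0.5 and 1 log2 units, and release changes at 35.8%, 77.6% and 98.5% for 0.5, 1 and 2. Level changes between cycles were recovered at 38.8%, 89.6% and 93.9% for 0.25, 0.5 and 1, and amplitude changes at 10.4%, 59.7% and 90.9%. Dye bias was recovered at 58.2%, 89.6% and 98.5% for 0.1, 0.25 and 0.5. The median error of the peak time was 0.791 min over 164 recovered genes, and simulated periods of 58, 66 and 74 min were estimated as 58, 65 and 74 min over 58 genes.

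Alternatives set beforehand were other periods, trends, harmonics, windows, time points, errors with lag-1 correlation, median centring, quantile normalization, filters, date batch as a block, stricter thresholds, leaving out each replicate, and leaving out each time point of the release comparison. Alternatives added after seeing the data were values at the limit set to missing, leaving out 105 min or 105, 110 and 115 min, a lag-1 correlation taken from called genes, removal of a trend on coding length, and 65 to 80 min as the later times of the release comparison.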

Results

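The series followed budding yeast of the laboratory strain W303 through 2 cell cycles after release from alpha factor, the mating pheromone that holds MATa cells in G1. Total RNA was sampled every 5 min from 0 to 120 min, which gave 25 time points. Each sample was hybridised against RNA of an asynchronous culture on 2 arrays with the dyes exchanged, 50 arrays in all. The arrays with the sample in Cy3 are replicate 1 and those with the sample in Cy5 are replicate 2. These pairs are technical repeats per the labels, so they were averaged and each time point counted once. No label names a second culture, so the limma p-values of single genes below measure the spread between time points of a single course, which may be partly technical. Those for dye bias measure the spread between dye-swap pairs. Fisher's exact tests and permutations of gene labels count genes as units, and genes are not independent. The number of arrays limits the precision. Across 6204 open reading frames, the log ratios of a dye-swap pair correlated with Pearson r from 0.196 to 0.673 (median 0.472 over 25 pairs), and with a median of 0.711 once frames with a value at the deposited limit were set aside. Of 709 values at that limit, 142 lay on the 45 min array with the sample in Cy3, against a median of 7.5 per array.

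The first question was which genes rose and fell with the cell cycle, and in what order. Of the 23 lists, histones had the highest median amplitude of periodic members (1.62 log2 units), followed by the pheromone response (1.15), MATa-specific (1.13) and SIC1 cluster (1.13) lists. Fitted by cycle, these medians went from 1.42 to 0.72 for the pheromone response and from 1.70 to 0.69 for MATa-specific genes. For the SIC1 cluster the median went from 0.68 to 1.22. The amplitudes of the mating lists thus take in their fall after release. All 9 histone genes, which encode the proteins that package DNA, were periodic and peaked together at 31.6 min (circular SD 0.553 min over 9 genes). Among them HTA2 had a fitted amplitude of 1.72 ± 0.16 log2 units (SE, n = 25 time points), a 10.9-fold difference between peak and trough. EGT2, which acts in cell separation after division, had the largest amplitude of the genes periodic in both dye orientations, 1.81 ± 0.21 log2 units (SE, n = 25) or 12.4-fold, with its peak at 7.81 ± 1.20 min. That fit also takes in a rise of its level between the cycles. Fitted by cycle, the amplitude of EGT2 was 0.55 and then 1.44 log2 units. Its highest value was at 75 min, and at 10 min it was at -3.82. RNR1, which encodes the large subunit of the ribonucleotide reductase that makes DNA precursors, swung 9.58-fold and peaked at 21.8 ± 1.58 min.

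The 12 widest swings among genes that passed in each dye orientation on its own included 6 histone genes. HTA1, HHF1, HTB2, HHF2 and HTB1 had amplitudes of 1.65, 1.63, 1.62, 1.62 and 1.48 log2 units beside HTA2. The others were EGT2, RNR1, TOS6 (1.65 ± 0.25 log2 units, peak at 28.3 min), the secreted cell wall protein gene HSP150 (1.56 ± 0.10 log2 units, peak at 6.87 min), the daughter-cell gene DSE2 (1.45 ± 0.35 log2 units, peak at 12.7 min) and ASH1 (1.43 ± 0.09 log2 units, peak at 4.24 min), a repressor of mating-type switching in daughter cells. In the fit of both, the smallest adjusted p among them was 1.41e-09, for HSP150, and the largest was 0.0081, for DSE2.

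Counted from 0 min, the MCM cluster had the earliest mean peak of the lists of core cell cycle genes, at 4.10 min (circular SD 4.68 min). It holds the replicative helicase genes MCM2 to MCM7, the helicase loader gene CDC6, CLN3 and SWI4. Periodic members of the pheromone response, MATa-specific and oxidative phosphorylation lists had earlier means, at 1.63, 1.96 and 3.23 min. In that list 8 of 9 genes were periodic, and 9 when adjusted over the list alone, among them MCM5 (1.16 ± 0.20 log2 units), MCM7 (0.90 ± 0.11) and MCM3 (0.76 ± 0.09). The SIC1 cluster, a set of genes of late mitosis and early G1 that includes the cyclin-dependent kinase inhibitor gene SIC1, peaked at 8.07 min with 16 of 18 genes periodic and 16 adjusted over the list alone. DSE4, a glucanase gene of daughter cell separation, had an amplitude of 1.36 ± 0.20 log2 units there. The fitted peak of this list was not seen in cycle 1, where its mean fell from -0.39 log2 units at 0 min to -1.20 at 10 min. In cycle 2 the list mean was highest at 75 min (0.66). Cohesion and repair genes peaked at 22.0 min (11 of 13 periodic, 12 adjusted over the list alone), led by the cohesin subunit gene MCD1 (1.42 ± 0.21 log2 units) with MSH6, PDS5 and SMC3 at 0.94, 0.93 and 0.87. DNA replication genes peaked at 22.8 min (17 of 18, and 17 adjusted over the list alone). There the thymidylate synthase gene CDC21, the polymerase gene POL1 and the sliding clamp gene POL30 had amplitudes of 1.13, 1.09 and 1.08 log2 units. G1 regulators peaked at 23.5 min (15 of 16, and 15 adjusted over the list alone). SVS1 reached 1.42 ± 0.21 log2 units, the G1 cyclin gene CLN2 1.34 ± 0.14, the cyclin gene PCL1 1.30 ± 0.22 and CSI2 1.22 ± 0.16. The S phase cyclin gene CLB5 was the member that did not pass.

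Spindle and kinetochore genes had their mean peak at the same 31.6 min as histones with a wider spread (circular SD 6.75 min, 26 of 31 periodic, 28 adjusted over the list alone). SPC98 and SPC97, components of the gamma-tubulin complex, peaked at 32.5 and 30.1 min, the kinesin gene CIN8 at 31.3 min, and the spindle midzone gene ASE1 at 55.2 min. The CLB2 cluster of mitotic genes peaked at 53.8 min (circular SD 3.87 min, 16 of 17 periodic, 17 adjusted over the list alone). Among these HOF1 and CHS2, which act in cytokinesis and septum formation, had amplitudes of 1.23 ± 0.23 and 1.17 ± 0.15 log2 units, BUD4 0.94 ± 0.14 and the mitotic cyclin gene CLB1 0.94 ± 0.17. Of 8 differences between successive lists tested by permutation of gene labels, 5 passed. The SIC1 cluster followed the MCM cluster by 3.97 min (two-sided permutation p = 0.0194, adjusted 0.0310, 8 and 16 genes), and histones followed G1 regulators by 8.08 min (permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted 2.67e-04). Cohesion and repair, DNA replication and G1 regulators were not ordered by this test: the gaps were 0.830 min (permutation p = 0.501, adjusted 0.668) and 0.689 min (permutation p = 0.636, adjusted 0.727). Nor were histones and spindle and kinetochore genes, with a gap of 0.0302 min (permutation p = 0.987, adjusted 0.987).

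**Figure D1:**
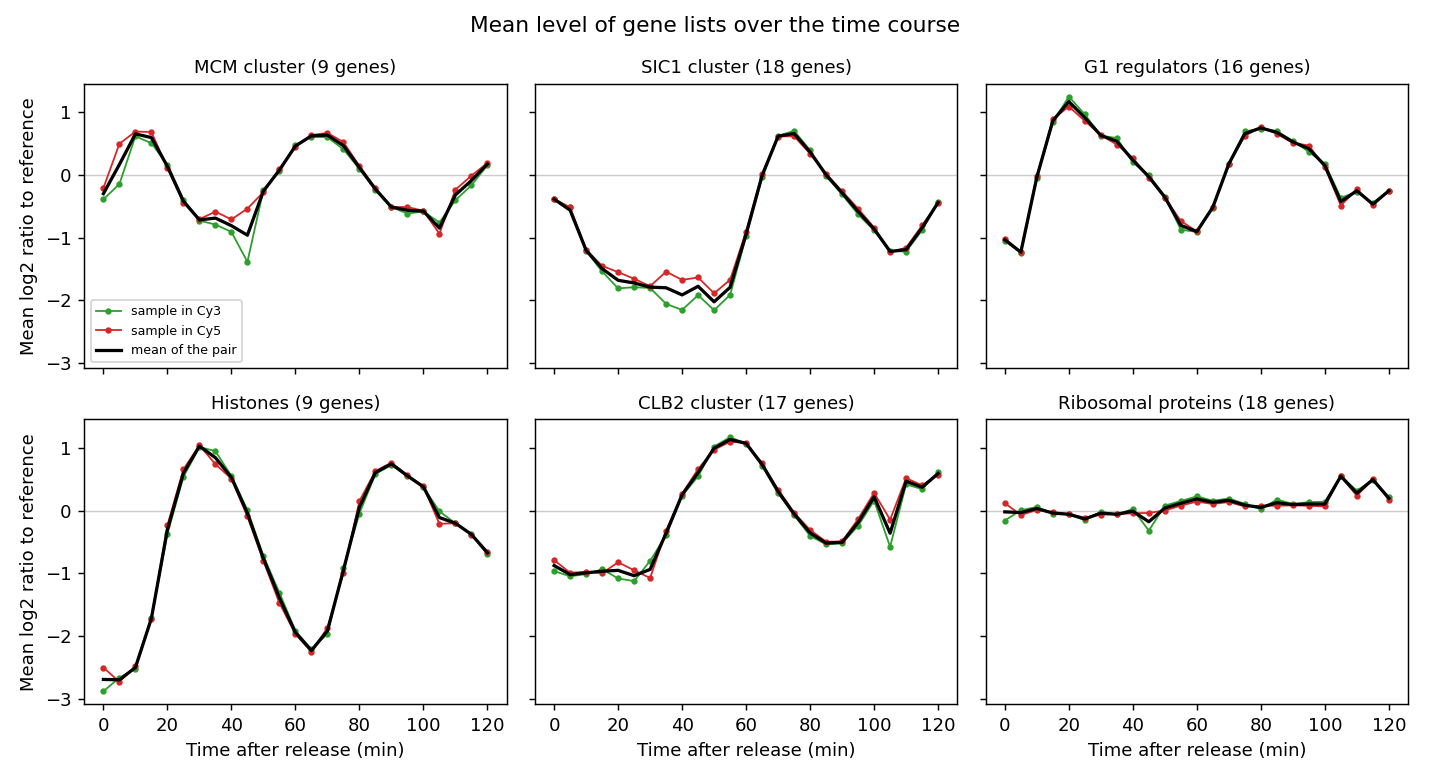
Mean log2 ratio to the asynchronous reference (vertical axis) against time after release in min (horizontal axis) for 6 gene lists; points are replicate 1 (sample in Cy3) and replicate 2 (sample in Cy5), and the black line is their mean. Histones reached their highest means at 30 and 90 min and the MCM cluster at 10 and 70 min, while the ribosomal protein mean went from 0.11 at 100 min to 0.55 at 105 min.

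Among 18 transcription regulators of the cell cycle, 16 were periodic, and 16 adjusted over the list alone. SWI4, whose product activates G1 transcription, peaked at 15.9 ± 1.96 min, followed by STB1 at 18.4 min, the repressor gene YOX1 at 21.1 min, TOS4 at 24.2 min, HCM1 at 24.6 min, PLM2 at 25.8 min and WHI5 at 27.9 min. SWI6, NRM1, NDD1, MBP1, FKH1 and YHP1 peaked between 29.2 and 42.8 min. SWI5, which encodes an activator of genes of the M to G1 transition, peaked at 51.4 ± 1.78 min. FKH2 (adjusted p = 0.288) and MCM1 (adjusted p = 0.333) did not pass the limma F test, although FKH2 passed with replicate 2 alone (adjusted p = 0.0020) and without 0, 5, 10 and 15 min (adjusted p = 0.0280).

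**Figure D2:**
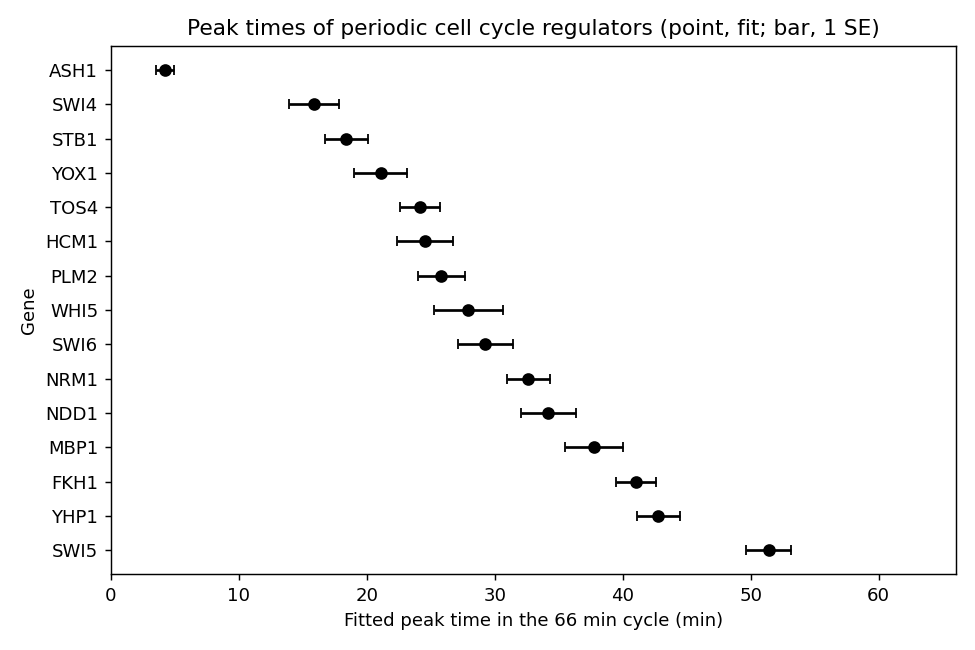
Fitted peak time in min within the 66 min cycle (horizontal axis) of 15 of the 16 periodic transcription regulators (vertical axis); points are the fitted times and bars are 1 SE over 25 time points. The peaks drawn run from ASH1 at 4.24 min to SWI5 at 51.4 min.

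Lists outside the core cell cycle genes differed in how many members were periodic. Phosphate genes had 10 of 12 (11 adjusted over the list alone) and a mean peak at 60.3 min, with the acid phosphatase genes PHO3, PHO5, PHO12 and PHO11 at amplitudes of 0.93, 0.88, 0.63 and 0.60 log2 units. Cell wall genes had 13 of 16 (14 adjusted over the list alone), led by CRH1 at 1.02 ± 0.10 log2 units, MNN1 at 0.96, GAS3 at 0.78 and CWP1 at 0.67. Ribosome biogenesis genes had 11 of 19 (14 adjusted over the list alone), all shallow, with NSR1, NOP7, RPA135 and RPA43 between 0.22 and 0.27 log2 units, and a mean peak at 47.2 min. No ribosomal protein gene of 18 was periodic in the limma F test, none adjusted over the list alone and none with lag-1 correlated errors. In that list 2 had an unadjusted p under 0.05, 5 passed without 105, 110 and 115 min and 1 without 0 to 15 min. In the pheromone response list 5 of 21 were periodic (5 adjusted over the list alone), namely FAR1, BAR1, STE2, GPA1 and PRM1. Of the MATa-specific genes BAR1, STE2, MFA2 and STE6 were, 4 of 7 (4 adjusted over the list alone). Stress genes had 9 of 17 (9 adjusted over the list alone), with TSL1, SSA1, HSP42 and HSP26 at 0.40, 0.34, 0.32 and 0.31 log2 units. Proteasome genes had 14 of 29 (14 adjusted over the list alone), led by RPN12 at 0.27 log2 units. Oxidative phosphorylation genes had 9 of 24 (9 adjusted over the list alone), led by the succinate dehydrogenase genes SDH2 and SDH1 at 0.42 and 0.35. Glycolysis genes had 5 of 16 (2 adjusted over the list alone), and reference genes TAF10 and TFC1 2 of 7 (2 adjusted over the list alone, and 5 periodic without 105, 110 and 115 min). Methionine genes had MET3 alone of 14 (0 adjusted over the list alone), meiosis genes SPS4 alone of 16 (1 adjusted over the list alone), and MATalpha-specific genes 0 of 4 in limma (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05). In both dye orientations fitted separately, 2 of the 29 proteasome, 6 of the 19 ribosome biogenesis and 1 of the 16 glycolysis genes were periodic. Without 0 to 15 min the periodic members numbered 8 for the proteasome, 14 for oxidative phosphorylation, 8 each for the pheromone response and glycolysis, and 5 for methionine genes.

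In total 2089 of 6204 open reading frames (33.7%) were periodic at a period of 66 min by limma's moderated F test, 267 of them with an amplitude of at least 0.5 and 56 with at least 1 log2 unit. The same test passed 990 genes at a period of 50 min, 2186 at 60 min, 1438 at 80 min and 1214 at 120 min, so the count alone does not tell a cycle of 66 min from slower courses. The period came from 60 genes of 4 lists (bootstrap SD 1.35 min, 95% interval 63 to 69 min), so the high shares in the G1 regulator, histone, CLB2 and SIC1 lists are not independent of it. The bootstrap drew genes, so its interval is a spread between genes of a single course. All tested genes gave 61 min. Within 0 to 60 and 65 to 120 min, list means were highest at 20 and 80 min for G1 regulators and 30 and 90 min for histones. They were highest at 0 and 75 min for the SIC1 cluster and 55 and 65 min for the CLB2 cluster. The maxima at 0 and 65 min lie at the edge of a window and are not peaks. The CLB2 cluster mean was still falling at 65 min (0.74), reached -0.52 at 85 min and was back at 0.59 at 120 min, the last time. Fitted alone, replicate 1 gave 1702 periodic genes and replicate 2 gave 1479, with 1024 in both against 406 for independent calls. Both fits used the same RNA samples, so the calls could not be independent, and the excess speaks only to repeatability across dyes. By two-sided Fisher's exact tests over 23 lists, periodic members were over-represented in 12 lists, from spindle and kinetochore genes (26 of 31, adjusted p = 2.60e-07) to ribosome biogenesis (11 of 19, adjusted p = 0.0495), and under-represented among ribosomal protein (0 of 18, adjusted p = 0.0016) and meiosis genes (1 of 16, adjusted p = 0.0302). Neither under-representation passed without 105, 110 and 115 min (5 of 18, adjusted p = 0.280, and 3 of 16, adjusted p = 0.124). Methionine genes were then under-represented (1 of 14, adjusted p = 0.0114). Without 0 to 15 min, stress genes (11 of 17, adjusted p = 0.0314) and oxidative phosphorylation genes (14 of 24, adjusted p = 0.0452) were over-represented by the same test. The arrays at 105 min deviated from the mean of their neighbours in time by a root mean square of 0.51 log2 units, against 0.34 at the next highest time, and without 105, 110 and 115 min, an alternative chosen after seeing the data, 2602 genes were periodic, of which 1997 were also among the 2089. The G1 cyclin gene CLN3 and WHI5 passed with replicate 1 (adjusted p = 2.86e-07 and 1.52e-04) but not with replicate 2 alone (0.0975 and 0.0839). The same was so for SPS4, MET3, TAF10 and MBP1 (adjusted p = 0.257, 0.0627, 0.0791 and 0.0538 with replicate 2), and NOP7 did not pass with replicate 1 alone (0.0626). DSE2 did not pass without a linear term (adjusted p = 0.150) or at a period of 60 min (0.192).

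The second comparison set the first cycle (0 to 55 min) against the second (60 to 115 min), 12 time points each. MFA1, which encodes the a-factor pheromone, went from 3.81 log2 units at 0 min to -1.01 at 60 min and was not periodic over the whole course. A cosine fitted to it had an amplitude of 2.51 log2 units in cycle 1, which takes in that fall, and 0.37 in cycle 2. The limma F test on sine and cosine together gave an adjusted p = 1.09e-04. Its mean level fell by 1.97 ± 0.46 log2 units (SE, n = 12 against 12 time points), to 0.256 of the level in cycle 1. EGT2 rose 8.34-fold between the cycles (3.06 ± 0.22 log2 units, adjusted p = 1.19e-08) and its amplitude went from 0.55 to 1.44 log2 units. Replication genes swung less in cycle 2: the median amplitude ratio of cycle 2 over cycle 1 was 0.564 over 17 periodic DNA replication genes, and all 17 had a smaller amplitude. All 9 histone genes also had smaller amplitudes, with a median ratio of 0.737.

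The fitted cosine differed between the cycles for 1451 of 6204 genes, with a smaller amplitude in cycle 2 for 816 and a larger one for 635, and 537 of the 1451 were periodic over the whole course. The adjusted p-values here belong to the limma F test on sine and cosine together. That test also responds to a shift in phase, and the amplitude difference alone was not tested. Besides MFA1, the largest decreases were in the a-agglutinin genes AGA2 (amplitude fell by 2.09 log2 units, adjusted p = 9.74e-04) and AGA1 (fell by 1.70, adjusted p = 0.0150) and in the mating genes ASG7 (fell by 1.41, adjusted p = 0.0145) and PRM3 (fell by 1.33, adjusted p = 0.0042). The largest increases were in YGP1, a secreted glycoprotein gene (1.38 log2 units, adjusted p = 0.0030), HO, the mating-type switching endonuclease (1.33, adjusted p = 0.0024), the retrotransposon frames YBR012W-A and YAR010C (1.26 each, adjusted p = 0.0018 and 0.0033) and the cyclin gene PCL9 (1.23, adjusted p = 1.33e-06). AGA2, AGA1, ASG7, PRM3, YBR012W-A and YAR010C were not periodic over the whole course, whereas YGP1, HO and PCL9 were. Ty frames are near-identical copies, so their values are uncertain. Without 105, 110 and 115 min AGA1, ASG7, YAR010C and YBR012W-A no longer passed (adjusted p = 0.0612, 0.0761, 0.113 and 0.0705), with amplitude changes of -1.77, -1.41, 0.50 and 0.57 log2 units.

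By list, 13 of 18 DNA replication genes changed in their cosine, all 13 with a smaller amplitude in cycle 2 (17 adjusted over the list alone), as did 8 of 16 G1 regulators (11 adjusted over the list alone), 9 of 17 CLB2 cluster genes (11), 6 of 13 cohesion and repair genes (9), 9 of 9 histones (9) and 6 of 7 MATa-specific genes (7). Median amplitude ratios of periodic members were 0.521 for cohesion and repair, 0.698 for the CLB2 cluster and 0.715 for G1 regulators. They were 0.396 for stress, 0.399 for MATa-specific, 0.508 for pheromone response and 0.598 for proteasome genes. The SIC1 cluster went the other way, with a median ratio of 1.58 and a larger amplitude in 15 of its 16 periodic genes, and the MCM cluster had a ratio of 1.06. Phosphate genes (1.55, larger in 8 of 10), oxidative phosphorylation genes (1.60, larger in 8 of 9) and ribosome biogenesis genes (1.26, larger in 6 of 11) also had median ratios above 1. The samples at 105, 110 and 115 min moved with these ratios. Without them the median ratio was 0.799 for DNA replication, 0.843 for cohesion and repair, 0.864 for G1 regulators, 0.889 for the CLB2 cluster, 0.817 for histones, 1.89 for the SIC1 cluster and 1.06 for oxidative phosphorylation.

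**Figure D3:**
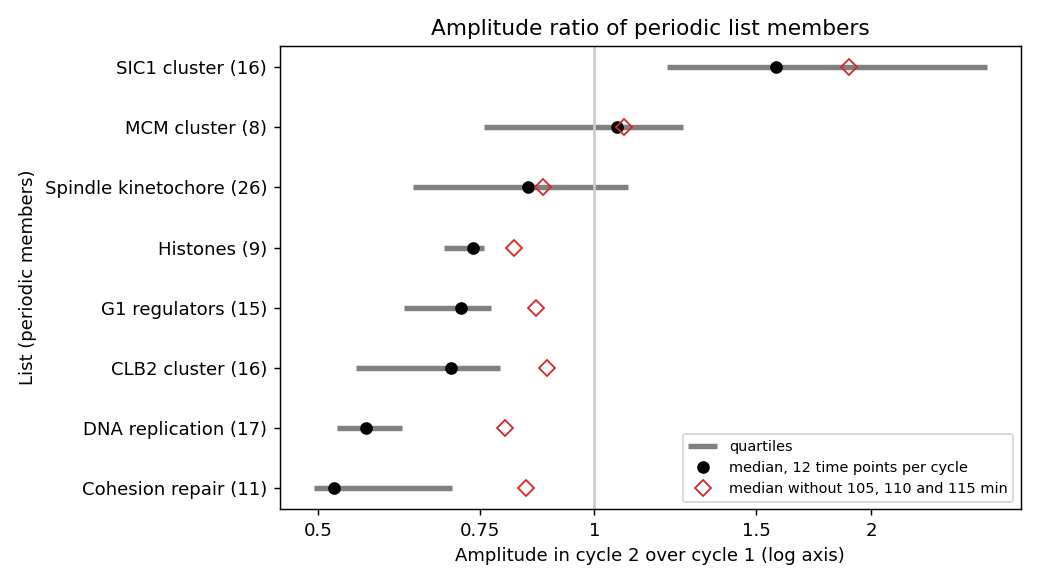
Amplitude in cycle 2 over cycle 1 (horizontal log axis) of the periodic members of 8 gene lists (vertical axis, number of genes in brackets); black points are medians with grey bars for quartiles, and red diamonds are medians without 105, 110 and 115 min. Of the 8 lists drawn, DNA replication and cohesion and repair have the lowest medians, 0.564 and 0.521, and the SIC1 cluster lies at 1.58.

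Mean level was higher in cycle 2 for 637 genes and lower for 649. The largest increases after EGT2 were in the uncharacterised frames YBR013C (2.70 ± 0.78 log2 units) and YIL102C (2.34 ± 0.41), the multigene family member COS12 (2.21 ± 0.79, uncertain because its copies are similar) and DSE4 (2.10 ± 0.22). The largest decreases besides MFA1 were in AGA1 (fell by 1.92 ± 0.39), the retrotransposon frames YIL082W-A (fell by 1.88 ± 0.27) and YIL082W (fell by 1.47 ± 0.25), and the mating gene FIG1 (fell by 1.69 ± 0.36). Without 105, 110 and 115 min, which leaves fewer time points, COS12 (2.28 ± 0.92) and YBR013C (1.99 ± 0.81) did not pass (adjusted p = 0.0749 and 0.0766). In the SIC1 cluster 14 of 18 genes were higher in cycle 2 (15 adjusted over the list alone, median 1.05 log2 units), in the CLB2 cluster 9 of 17 (10, median 0.44), among ribosomal proteins 14 of 18 (14, median 0.24) and in oxidative phosphorylation 10 of 24 (11, median 0.17). The CLB2 cluster had 4 higher genes under quantile normalization and 15 without 105, 110 and 115 min, and oxidative phosphorylation 16 without these times and 6 with the trend on coding length removed. Methionine genes were lower in 11 of 14 (11, median -0.51), pheromone response genes in 10 of 21 with 1 higher (12, median -0.62), and stress genes in 9 of 17 with 3 higher (13, median -0.25; 0 higher without 105, 110 and 115 min). Coding sequences in the ribosomal protein list are short (median 678 bp), and at 105 min that list lay 0.33 log2 units above its neighbours in time, while the CLB2 cluster lay at -0.49 and methionine genes at -0.40. Without 105, 110 and 115 min, 12 of 18 ribosomal protein genes were still higher in cycle 2, with a median of 0.16.

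For these lists the medians kept their sign under median centring and quantile normalization. With camera's preset correlation the SIC1 and CLB2 clusters, ribosomal proteins, oxidative phosphorylation, histones (9 genes, median 0.37, none passing singly but 3 without 105, 110 and 115 min) and proteasome genes (4 of 29 higher) were higher in cycle 2 and the methionine, pheromone, stress and ribosome biogenesis (3 of 19 lower, 9 under quantile normalization and 1 without 105, 110 and 115 min) lists lower. None held with an estimated correlation, where the lowest adjusted p was 0.0894, for the SIC1 cluster, and the next was 0.173. Among cell wall genes 3 rose and 2 fell, and the median (-0.08) and the mean (0.01) differed in sign. Dates in the labels split near 60 min in both dye orientations, so the cycle and the date batch cannot be told apart in this comparison. The count of changed cosines was 711 without 105, 110 and 115 min, 677 at a period of 60 min and 792 for 15 to 55 against 75 to 115 min.

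The third comparison asked what set freshly released cells apart from cells near the same phase 1 cycle later, as 0, 5, 10 and 15 min against 60, 65, 70 and 75 min. Several mating genes were higher just after release, 5 of the 21 in the pheromone response list among them. That list had an adjusted p = 0.682 by camera with an estimated correlation. MFA1 was 21.1-fold higher (4.40 ± 0.22 log2 units, SE, n = 4 against 4 time points, limma adjusted p = 3.41e-05), AGA1 13.6-fold (3.76 ± 0.66, adjusted p = 0.0084), AGA2 11.4-fold (3.51 ± 0.38, adjusted p = 0.0012) and FIG1 8.46-fold (3.08 ± 0.72, adjusted p = 0.0269). In the CLB2 and SIC1 clusters 15 of 17 and 7 of 18 genes were lower, with EGT2 11.6-fold (fell by 3.54 ± 0.53, adjusted p = 0.0044) and the septum gene CHS2 6.11-fold (fell by 2.61 ± 0.30, adjusted p = 0.0015) lower than at 60 to 75 min. In all, 569 genes were higher and 345 lower at 0 to 15 min, 85 and 52 of them by at least 2-fold. At a period of 66 min the later window lies 6 min earlier in phase, so phase can add to the difference where a list changes steeply. At 61 min, the period over all tested genes, the windows lie closer in phase. The CLB2 cluster had a mean of 1.07 log2 units at 60 min and 0.31 at 70 min. Against 65 to 80 min, chosen after seeing the data, 583 genes were higher and 382 lower. Of the 914 calls 771 were kept with the same sign. Here 14 of 17 CLB2 cluster genes were lower with a median of -1.08 instead of -1.46.

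**Figure D4:**
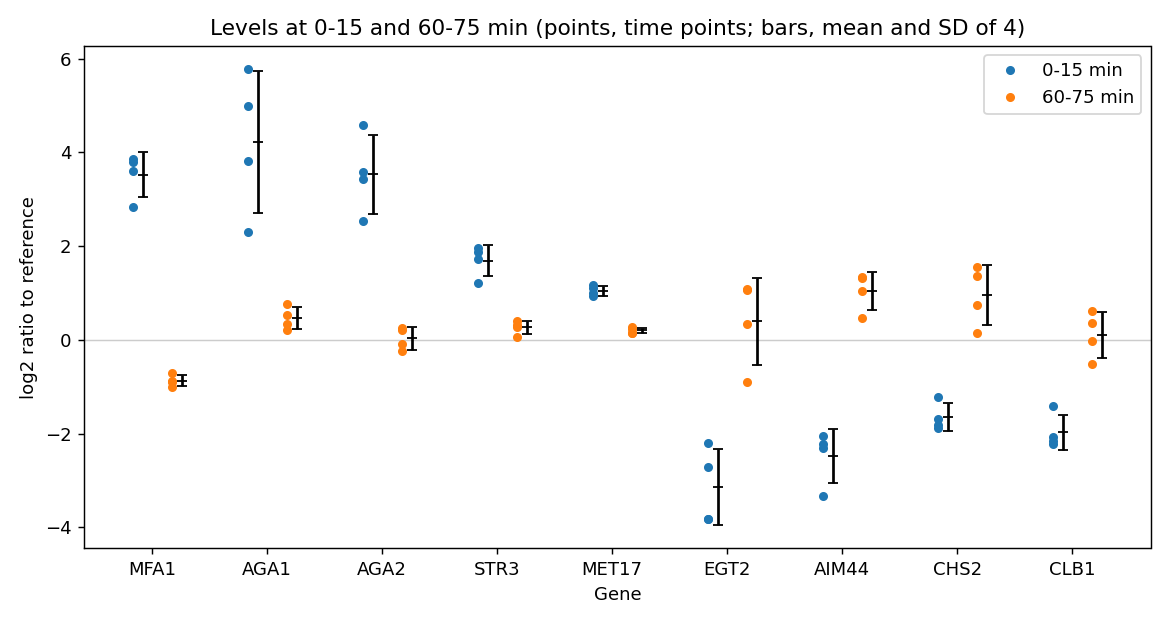
Log2 ratio to the asynchronous reference (vertical axis) of 9 genes (horizontal axis) at 0 to 15 min (blue) and 60 to 75 min (orange); points are time points and bars are the mean and SD of 4. The means of MFA1 are 3.53 and -0.87 and those of EGT2 are -3.15 and 0.39.

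The direction of the ratios was read from pheromone genes at 0 min, so their position above and not below the reference in the arrested cells was set by that reading. In this direction AGA1 was at 55.2-fold, FIG1 at 41.3-fold, PRM1 at 26.8-fold, ASG7 at 24.4-fold, AGA2 at 24.2-fold and FIG2 at 22.8-fold the reference level. FUS1, a gene of cell fusion, was at 13.2-fold. By 10 min the log2 ratio of FUS1 had gone from 3.72 to 0.51 and that of the transcription factor gene KAR4 from 3.39 to 0.42, whereas MFA1 went from 3.81 to 3.61 and AGA2 from 4.60 to 3.44. Each value is the mean of 1 dye-swap pair. In the pheromone response list 5 of 21 genes passed the comparison of 4 against 4 time points (5 adjusted over the list alone), namely AGA1, FIG1, ASG7 (2.71 ± 0.60), PRM3 (2.66 ± 0.45) and FIG2 (2.45 ± 0.58). FUS1 (1.90 ± 0.68, adjusted p = 0.102), KAR4 (1.78 ± 0.67, adjusted p = 0.117) and FUS3 (0.82 ± 0.49, adjusted p = 0.305) did not, nor did STE12 (-0.13), FAR1 (-0.25) and MSG5 (-0.52). Of 7 MATa-specific genes, MFA1, AGA2 and ASG7 passed (3 adjusted over the list alone), and of 4 MATalpha-specific genes none did in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, median 0.04).

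The rest of the 10 largest increases were YMR173W-A (2.60 ± 0.09 log2 units), YPL088W (2.48 ± 0.17) and YNL208W (2.32 ± 0.07). YMR173W-A overlaps another gene, so its value is uncertain. The rest of the 10 largest decreases were AIM44 (fell by 3.52 ± 0.31), MRH1 (fell by 3.19 ± 0.34), PCL9 (fell by 3.09 ± 0.24), YIL102C (fell by 2.86 ± 0.58, with -5.50 in replicate 1 and -0.34 in replicate 2), DSE4 (fell by 2.61 ± 0.56, adjusted p = 0.0733 with the pair of times as a block), HOF1 (fell by 2.53 ± 0.28), the plasma membrane gene SUR7 (fell by 2.42 ± 0.32) and DSE3 (fell by 2.30 ± 0.43). In the CLB2 cluster 15 of 17 genes were lower (16 changed adjusted over the list alone, median -1.46), among them HST3 (fell by 2.11 ± 0.24), CLB1 (fell by 2.08 ± 0.27) and SWI5 (fell by 1.30 ± 0.25). In the SIC1 cluster 7 of 18 were lower (8 changed adjusted over the list alone, median -0.85).

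Methionine and sulfur genes, which take up sulfate and build methionine and cysteine, were higher in 11 of 14 (11 adjusted over the list alone, median 0.67 log2 units). STR3 led at 1.42 ± 0.16 (adjusted p = 0.0015), with MET3 at 1.15 ± 0.17, MET14 at 0.89 ± 0.16 and MET17 at 0.85 ± 0.07. The list mean was 0.96 log2 units at 5 min and 1.20 at 10 min, but also 0.97 at 35 min and 0.95 at 40 min, before 0.21 at 55 min. Stress genes were higher in 6 of 17 (7 adjusted over the list alone, median 0.20), with HSP26 at 0.69, TPS2 at 0.63, SSA4 at 0.58 and HSP30 at 0.55. Oxidative phosphorylation genes were lower in 9 of 24 (16 changed adjusted over the list alone, median -0.33), with CYT1 (fell by 0.78), RIP1 (fell by 0.77), QCR2 (fell by 0.58) and ATP3 (fell by 0.55). Ribosomal protein genes RPL5 (fell by 0.33) and RPL28 (fell by 0.22) were the 2 of 18 that passed (1 adjusted over the list alone). Among cell wall genes GSC2, CHS3 and KRE6 were among 5 of 16 changed (5 adjusted over the list alone), SUN4 fell by 1.17, and 3 were higher and 2 lower. Among 31 spindle and kinetochore genes SPC25 and NDC80 were higher and ASE1 and TUB2 lower (3 changed adjusted over the list alone), and the median (0.08) and the mean (-0.02) differed in sign. Of 18 transcription regulators 3 were lower, SWI5 and ASH1 among them (4 changed adjusted over the list alone). Phosphate genes had PHO89 higher and PHO3 and VTC1 lower (3 changed of 12 adjusted over the list alone). Meiosis genes had DMC1 and SPO11 higher of 16 (3 changed adjusted over the list alone). Reference genes had ACT1 higher (0.66 ± 0.11) and TFC1 lower (fell by 0.59 ± 0.12) of 7 (3), and proteasome genes had PRE9 higher of 29 (0). No G1 regulator, DNA replication, cohesion and repair, histone, MCM cluster, glycolysis or ribosome biogenesis gene passed in limma (0 adjusted over the list alone in each, and 1, 0, 1, 2, 0, 2 and 2 in that order at an unadjusted p under 0.05). With the pair of times as a block CHS3, HSP30, PHO3, VTC1, RPL28, SUN4, TUB2, DMC1 and SPO11 no longer passed (adjusted p from 0.0533 to 0.109). In that fit 3 of 17 stress genes were higher and 6 of 9 histone genes lower. It also had 2 G1 regulators lower and 1 cohesion and repair gene higher. Against 65 to 80 min PHO3, VTC1, NDC80 and ASE1 did not pass (adjusted p = 0.237, 0.194, 0.131 and 0.168). The histone median was -0.55 log2 units, but 0.49 under quantile normalization and -1.10 against 65 to 80 min. The G1 regulator median was -0.23, and -0.77 against 65 to 80 min. For DNA replication the median (0.02) and the mean (0.04) were above 0, but the median was -0.03 under quantile normalization and -0.29 against 65 to 80 min, and camera's direction was down.

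With camera's preset correlation 12 of 23 lists passed. These were the CLB2 and SIC1 clusters, transcription regulators, histones, ribosomal proteins, oxidative phosphorylation, glycolysis and phosphate genes toward lower levels (histones upward in median under quantile normalization), and the pheromone, MATa-specific, methionine and stress lists toward higher levels. None held with an estimated correlation, where the lowest adjusted p was 0.450. Under quantile normalization the median went from 1.58 to 0.86 for the pheromone and to 1.01 for the MATa-specific list. It went from 0.67 to 0.41 for methionine, from -0.33 to -0.50 for oxidative phosphorylation, from -0.27 to -0.17 for transcription regulators (-0.44 against 65 to 80 min) and from -0.31 to -0.18 for phosphate genes. By fry, whose p-value tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, the CLB2 cluster (adjusted p = 0.0068), MATa-specific (0.0098), ribosomal protein (0.0064), stress (0.0064), methionine (0.0064) and oxidative phosphorylation (0.0124) lists passed. With the pair of times 60 min apart as a block, 477 genes were higher and 285 lower, and 662 of the 914 calls were kept.

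Within a single date batch, 0 to 15 min could be set only against 40 to 55 min (replicate 1) and 5 to 15 min only against 45 to 60 min (replicate 2). The early arrays are the same as in the comparison 1 cycle apart. The later times lie at another phase, near the fitted peaks of CHS2, SWI5 and ASE1 (55.5, 51.4 and 55.2 min). Differences here therefore mix phase with release, and by themselves cannot tell date batch from phase. MFA1 was then 4.60 and 4.30 log2 units higher, CHS2 -2.60 and -3.00, and STR3 0.95 and 1.15. MET3 was 0.24 and 0.75 log2 units higher (adjusted p = 0.536 and 0.10), MET17 0.18 and 0.50 (0.382 and 0.102) and MET14 1.26 and 0.86 (0.123 and 0.0125). Differences were also smaller for AIM44 (-0.64 and -1.03), MRH1 (-1.34 and -2.13), PCL9 (-0.08 and -0.82), RIP1 (-0.09 and -0.32), CYT1 (-0.32 and -0.24) and ATP3 (-0.21 and -0.22). So they were for SPC25 (0.12 and 0.14), SSA4 (0.32 and 0.23), HSP30 (0.37 and 0.42), PHO3 (-0.56 and -0.77) and RPL5 (-0.24 and -0.21), and in replicate 1 for SUN4 (-0.68), GSC2 (0.47) and KRE6 (0.18). They were larger for PHO89 (1.90 and 1.87), SWI5 (-1.85 and -2.05), TUB2 (-0.99 in replicate 2 and further down in replicate 1), TFC1 (-0.91 and -0.98) and ASE1 (-1.30 and -1.17). The methionine median was 0.32 and 0.57, that of oxidative phosphorylation -0.07 and -0.0049, and that of the SIC1 cluster 1.12 and 0.23, opposite in sign to the comparison 1 cycle apart. EGT2 (0.94), DSE4 (0.61), DSE3 (0.67), RPL28 (0.12), NDC80 (-0.32) and QCR2 (0.0062) changed sign within the replicate 1 batch, and ASH1 in both batches (1.48 and 0.71). Of the named genes that had not passed, FAR1 changed sign in both (1.81 and 0.33) and MSG5 within the replicate 1 batch (0.09). Leaving out 65 min gave 297 higher and 149 lower genes, 70 min 332 and 154, 75 min 376 and 222, 10 min 370 and 203, and 5 min 226 lower genes.

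The dye-swap pairs also gave the dye bias of each gene, as the mean over 25 pairs of the replicate 2 minus the replicate 1 ratio, divided by 2. The orientations shared no date batch, so what is called dye bias here cannot be told apart from a difference between dates. The largest biases were in YGL132W (2.08 ± 0.33 log2 units, SE, n = 25 pairs), the sporulation gene SSP2 (1.45 ± 0.32) and YDL032W (1.16 ± 0.29) toward Cy5, and in YNR071C (-1.77 ± 0.18), the transporter gene PDR18 (-1.37 ± 0.25) and AIF1 (-0.90 ± 0.25) toward Cy3. Of 6201 genes tested by limma, 2000 had a higher and 886 a lower ratio with the sample in Cy5, but 30 had a bias of at least 0.5 log2 units. Median centring of each array changed the split to 1450 higher and 1235 lower, and over all genes the median bias was 0.03 log2 units. By list, 6 of 7 MATa-specific, 12 of 29 proteasome, 8 of 16 cell wall and 7 of 18 SIC1 cluster genes had a higher ratio with the sample in Cy5, and 6 of 16 meiosis genes had a lower one.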

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

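The tests of a single array and of long RNA, the alternatives without 105, 110 and 115 min, and the random dealing and left-out genes of the offset test were chosen after the result was seen, and the genes of that test were not fixed beforehand. Among 142 groups of 4 time points, 3 held a value far from the other 3, against 5% by chance. YIL102C was at -0.88 log2 units at 0 min, SWI5 at -1.26 at 5 min and RPL5 at 0.27 at 60 min.

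The fitted cosine differed between the cycles for 1451 genes by the interaction test, 537 of them periodic over the whole course. The amplitude in cycle 2 minus that in cycle 1 was -2.15 log2 units for MFA1, -2.09 for AGA2, -1.70 for AGA1, -1.41 for ASG7 and -1.33 for PRM3. It was 1.38 for YGP1, 1.33 for HO, 1.26 for YBR012W-A, 1.26 for YAR010C, 1.23 for PCL9, 0.89 for EGT2 and 0.80 for DSE4. MFA1, AGA2, AGA1, ASG7, PRM3, YBR012W-A and YAR010C were not periodic over the whole course, and the cosine of MFA1 in cycle 1 takes in its fall after release. Of 100 swaps of times 60 min apart, only 1, the real order, gave as many, with 844 the highest of the others. Swaps break up runs of neighbouring times, so slow drift or date batch, which follows the same times, could also set the real order apart. This comparison excludes neither, and up to 844 genes passed with the times swapped. The same holds for the level, with 637 genes higher and 649 lower against 873 in all at most.

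The amplitude was smaller in cycle 2 for 60.7% of the 2089 periodic genes, with a median ratio of 0.83. Of the 267 with an amplitude of at least 0.5, it was smaller for 186, with a median ratio of 0.737 (quartiles 0.541 and 1.13). Without 105, 110 and 115 min the median ratio of these 267 was 0.877. Whether ratios were compressed on the later arrays stays open. Standing offsets of 161 genes that were not periodic had a slope of 0.869 ± 0.0662 on the arrays with the sample in Cy5 (0.753 with the sample in Cy3), within 0.1 of the ratio of all periodic genes, the bound fixed beforehand. Times dealt at random to both windows gave slopes from 0.839 to 1.19 (95% of 1000 draws). The slope with the sample in Cy5 lies within them, so it does not tell compression from no change. Draws as low were counted only for the slope with the sample in Cy5 (57 of 1000). The slope of 0.753 with the sample in Cy3 lies below the range, but it was not tested in this way, and nothing is concluded from it. Over the 94 genes without a release call the slope was 1.24. The rule for this verdict was made stricter after the slope was seen. Compression alone leaves out the SIC1 cluster and phosphate genes, whose ratios were 1.58 and 1.55. The RNA of the samples at 105 to 115 min stays open, since without them the second lowest ratio of the 4 lists that set the period was 0.864, and loss of synchrony, a biological explanation, was not tested.

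The arrays at 105 min were apart from their neighbours in time, with Ty elements, PMA2 and DED1 low (DED1 at -2.48 log2 units) and HAC1 (2.97), MSA1 (2.52), RPP2A (2.33) and YKR104W (2.32) high. HAC1 was high mostly on the array with the sample in Cy5 (5.03 against 0.90), where MSA1 was at 0.55, and MSA1 mostly on the other. The fault of a single array is argued against by a correlation of 0.439 across genes between the deviations of the 2 dye-swap arrays, though genes are not independent replicates. A large rise of stress genes is argued against too. The stress list deviated from all genes by -0.0387 log2 units (95% interval -0.31 to 0.17). A smaller rise stays open, because the list was not matched for length. Its median coding length was 1929 bp, and long frames were low at 105 min. Loss of long RNA stays open: Spearman's rho of the deviation with coding length was -0.194 and -0.410 in the 2 arrays, the first of which lies between the bounds set for the test. The neighbour at 110 min had a length trend of its own, which can weaken this test. Over pair means, rho of the level with coding length was -0.378 at 105, -0.269 at 110 and -0.305 at 115 min. The strongest at any other time was -0.181, at 40 min. The deviation was 0.20 for coding lengths up to 795 bp and -0.22 from 1932 bp, and only the array with the sample in Cy5 had a date batch of its own.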

How the results depend on the processing

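The alternatives without 105 min, without 105, 110 and 115 min, with values at the limit missing, with a correlation from called genes, with the coding length trend removed and against 65 to 80 min were chosen after the data were seen. The period was 61 min with all genes and otherwise 65 or 66. Periodic genes numbered 1296 at an adjusted p under 0.01, 817 with an amplitude of at least 0.25 and 1479 to 2797 otherwise. With date batch as a block they numbered 1994, of which 1633 were also called in the main fit. Filters on missing values removed no gene and say nothing. Changed cosines numbered 792 for 15 to 55 against 75 to 115 min, 677 at a period of 60 min, 711 without 105, 110 and 115 min and 2287 with lag-1 correlated errors, where the residual correlation of this fit was -0.174. They numbered 794 without replicate 1 and 1063 without replicate 2. The median amplitude ratio was 0.763 for 5 to 60 against 65 to 120 min, 0.935 under quantile normalization, 0.877 without 105, 110 and 115 min, 0.810 without 105 min and 0.825 to 0.843 without a replicate. Levels without a replicate were higher for 344 to 554 genes and lower for 419 to 589. The amplitude change of YIL082W-A became -0.35 without 105, 110 and 115 min. Changes that had not passed also turned: the amplitude of COS12 (-0.51) and YBR013C (-0.53) for 5 to 60 against 65 to 120 min, the amplitude of COS12 (-0.038) and the level of YGP1 (-0.32) for 15 to 55 against 75 to 115 min, and the amplitude of YBR013C from -1.60 to 0.87 without a replicate. Release counts were 297 to 621 higher and 149 to 436 lower when a time point or replicate was left out. Lower genes numbered 206 for 0 to 10 against 60 to 70 min, 545 within the Cy3 batch and 594 within the Cy5 batch. Under quantile normalization the median became 0.49 for histones, -0.026 for DNA replication and 0.093 for ribosome biogenesis. For 0 to 10 against 60 to 70 min STE12 became 0.047, FAR1 0.25 and MSG5 0.41, and the median -0.076 for DNA replication, -0.010 for cohesion and repair, 0.052 for ribosome biogenesis and 0.0085 for the proteasome. For 0 to 15 against 55 to 70 min FAR1 became 0.11, and the median 0.16 for G1 regulators, -0.022 for MATalpha-specific genes and 0.0019 for the proteasome. Against 65 to 80 min the median became -0.29 for DNA replication, -0.17 for cohesion and repair, -0.0073 for spindle, 0.051 for ribosome biogenesis, -0.028 for cell wall and 7.62e-04 for proteasome genes. With values at the limit missing MSG5 became 0.27 and the ribosome biogenesis median 0.0013. When a time point or replicate was left out, STE12 ranged from -0.45 to 0.025, FAR1 from -0.87 to 0.21 and MSG5 from -1.31 to 0.45, and the median from -0.66 to 0.16 for G1 regulators, -0.26 to 0.33 for DNA replication, -0.24 to 0.40 for cohesion and repair, -0.042 to 0.24 for meiosis, -0.11 to 0.073 for ribosome biogenesis, -0.11 to 0.27 for cell wall and -0.10 to 0.033 for proteasome genes. Within the Cy3 batch, where the later times lie at another phase, EGT2 was 0.94, DSE4 0.61, DSE3 0.67, RPL28 0.12, NDC80 -0.32, ASH1 1.48, QCR2 0.0062, FAR1 1.81, MSG5 0.087 and the median -0.30 for spindle, 1.12 for SIC1 cluster, 0.46 for MCM cluster and 0.11 for proteasome genes. Within the Cy5 batch ASH1 was 0.71, FAR1 0.33 and the median -0.21 for spindle, 0.23 for SIC1 cluster, 0.37 for G1 regulator, 0.40 for MCM cluster and -0.047 for meiosis genes. Dye bias counts were 1227 higher and 538 lower in the first 12 pairs and 536 lower in the last 13. Apart from phase and the number of samples, the cause was not tested. Of 1419 values of named genes in the release comparison under alternatives, 1168 kept direction and side of the threshold, 213 no longer passed, 17 newly passed and 21 changed sign, 8 of these in genes that passed. Of 460 list medians 42 changed sign. By replicate number no paired analysis was possible between time points because the numbers name the dye orientations of 1 RNA, while dye bias was fitted within dye-swap pairs and the release also with times 60 min apart as a block. The number of arrays limits precision.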

Other observations

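The test of amino acid synthesis genes was chosen after the result was seen. Beyond sulfur genes, 12 of 31 other amino acid synthesis genes were higher at 0 to 15 than at 60 to 75 min and none was lower by limma (median 0.30 log2 units). The arginine genes ARG4 (1.28 ± 0.18 log2 units, SE, n = 4 against 4, adjusted p = 0.0034), ARG3 (1.21 ± 0.14) and ARG1 (1.18 ± 0.16) led, with the serine gene SER3 at 1.16 ± 0.17. Within a date batch ARG4 was 1.19 and 1.10 log2 units higher and ARG3 1.03 and 1.25, but the medians of the 31 genes were 0.16 and 0.21.

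Methionine and sulfur genes were higher at 0 to 15 min (median 0.67 log2 units, 0.41 under quantile normalization). Date batch cannot be told apart from the release as a source of part of it: the lower of the 2 medians within a batch was 0.321, just short of the bound that would have argued against it, and the other was 0.57. The list mean was as high at 35 and 40 min (0.97 and 0.95) as at 5 min (0.96), and 40 min is among the later times of the replicate 1 comparison. A wider rise of amino acid synthesis genes may be what the sulfur list shares in, but camera with an estimated correlation gave p = 0.0535 for the other amino acid list (1.66e-07 with the preset one), which leaves it open. A response to the fresh medium or the pheromone was not tested.

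For the count of periodic genes, 2089 compares with 1 at most in the others of 100 orders of the time points. This excludes an order of the samples without structure in time, but random orders also remove slow drifts and steps, and 1438 genes passed at a period of 80 min and 1214 at 120 min. For the release count, the real split of the 8 time points gave 914 genes, against 34 at most in the others of 35 splits. The split with 34 set 0, 5, 60 and 65 min against the rest. Every other split mixes early and late times, so drift or date batch could also set the real split apart, and neither is excluded. Groups did not overlap for 23.4% of genes. For exchangeable time points it would be 2.86%, but those of a single course are not exchangeable.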
